A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

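RNA was measured in 12 libraries of Saccharomyces cerevisiae strain MGD353-13D, 2 libraries in each of 6 groups. Per the labels, the cells grew in rich medium (YPD) to mid log phase, total RNA was depleted of ribosomal RNA, and directional sequencing libraries were made. Per the labels, the authors used bcl2fastq 2.17.1.14, TopHat and Cufflinks (the last 2 without a stated version) with the genome build sacCer3. The deposited table is a Cuffdiff gene table by library with 7126 gene identifiers. It holds expected counts of fragments, before any scaling, and the authors' FPKM (fragments scaled by transcript length and library size, after a library scaling factor). In the deposited expected counts, 97.8% of values were exactly whole, and 183 identifiers had a fractional value. The strand setting of the counting, the treatment of multiply mapped reads and the gene annotation used are not stated. Genes that overlap on opposite strands could therefore not be told apart.

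Identifiers were matched to the sacCer3 annotation, 6048 by locus tag and 114 by symbol, and 964 were not matched. The unmatched identifiers stayed in the tests and were left out in an alternative. A further 14 identifiers, which the file marks as too deep to estimate and lists at 0 in every library, were left out. Transfer RNA genes (299 identifiers) held 36 fragments in all libraries together, so transfer RNA was not analysed here. Gene copies were searched with blastn 2.17.0 among 6162 genes. Genes with at least 95% identity over at least 50% of their length (310 genes), and genes with at least 10% of their length inside another gene (231 genes), are called uncertain where they are named. Unmatched identifiers could not be checked for copies or overlaps.

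Library depth ran from 8652878 to 26041718 fragments. Counts were rounded to whole numbers. edgeR 4.0.16 in R 4.3.3 was run with its default expression filter, which kept 6361 of 7112 identifiers, and with TMM scaling. All 12 libraries entered a single quasi-likelihood fit with 6 groups, and each comparison was a contrast of that fit. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05 with no fold threshold. The error given beside a log2 fold change is its standard error, the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 10.2%. CPM values are those of edgeR with TMM-scaled library sizes. No spike-in was added per the labels, so all levels are relative to the rest of the RNA of a library. A count of 0 was read against a floor of 3 fragments in each library. Floors cover counting error only, and PCR copies were not removed by molecular identifiers.

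Gene lists were fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for named genes. Of the lists, 41 had at least 3 genes tested: Set1 complex, JmjC proteins, Set3 complex, Sir and telomere silencing factors, core histones, cytosolic ribosomal proteins, ribosome biogenesis, mitochondrial ribosomal proteins, phosphate regulon, galactose genes, methionine and sulfur assimilation, iron regulon, zinc regulon, ergosterol biosynthesis, phospholipid INO genes, environmental stress response (induced), heat shock chaperones, glucose-repressed carbon metabolism, hexose transporters, glycolysis, respiratory chain and TCA cycle (nuclear genes), amino acid biosynthesis (Gcn4 targets), purine biosynthesis (Bas1 targets), NAD biosynthesis, thiamine and vitamin B6 genes, nitrogen catabolite repressed genes, meiosis and sporulation, the seripauperin PAU family, DAN/TIR cell wall genes, the subtelomeric COS family, other subtelomeric genes, a-specific genes, alpha-specific genes, haploid-specific and pheromone response genes, cell wall integrity and surface, G1 and S phase, mitosis and M/G1, proteasome, DNA damage response, multidrug transporters and Pdr targets, and strain markers with the neighbours of the mutated loci. No identifier of the file matched a name on the list of Ty elements, so that list was not tested. Each list was tested with camera (limma 3.58.1, correlation between genes preset at 0.01, adjusted over the lists) for a shift relative to the other genes. The test was repeated with an estimated correlation, and fry tested whether the genes of a list moved, on balance, in 1 direction.

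Named genes were SDC1 and JHD2, the members of the Set1 complex, the 10 largest rises and 10 largest falls of each strain against WT (5 each way in other comparisons) among called genes with a mean of at least 5 CPM and separated groups, and up to 4 members of each list that was called or held 3 or more called genes. Where the largest falls or rises were mitochondrially encoded, the next nuclear genes were added after the values had been seen.

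Alternatives were RLE scaling, DESeq2 1.42.0, no filter beyond at least 1 fragment over all libraries, and a replicate block. Others were a fit of only the groups compared and limma-trend on log2(FPKM + 1). Mitochondrially encoded and structural RNAs (418 identifiers) were also left out, as was each library in turn (11 libraries per fit). Leaving out 684 unmatched identifiers, those not named as structural RNAs, was added after the data had been seen. The method was tested on a single simulated draw with the library sizes, WT means and dispersions of the data (6258 genes, 200 changed in Sdc1_mut beside a raised list of 40). In the data themselves 3342 of 6361 genes were called in Sdc1_mut against WT, so the simulated rates may not carry over to that comparison. It called 57.6% of genes changed 1.5-fold, 89.4% of those changed 2-fold and 95.4% of those changed 4-fold, and 6.03% of its calls were unchanged genes. In a simulated comparison with no change it called 0 genes. A simulated raised list of 40 genes gave a camera p of 1.2e-38 and an unchanged list a p of 0.59. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.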

Results

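RNA levels were measured in 6 yeast strains, with 2 libraries of each. Besides the wild type (WT), 3 strains carried changes in SDC1, which encodes the subunit of the Set1 histone H3K4 methyltransferase complex that holds the DPY30 motif. These were a gene deletion (Sdc1_KO), a deletion of the DPY30 motif (Dpy30_KO) and a point mutant (Sdc1_mut). Another strain lacked JHD2, the H3K4 demethylase gene (Jhd2_KO), and the last combined the point mutation with the JHD2 deletion (Sdc1_mut_Jhd2_KO). The title and design of the series set out to relate the Set1 complex and Jhd2 to H3K4 methylation. Methylation itself was not analysed here.

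The WT libraries held 26041718 and 24067151 fragments, those of Sdc1_KO 13597606 and 17597006, and those of Dpy30_KO 14180681 and 11442273. The Sdc1_mut libraries held 10807158 and 14637999 fragments, those of Jhd2_KO 8652878 and 12228952, and those of Sdc1_mut_Jhd2_KO 14283734 and 14017429. Fold changes are log2 values with their standard error, from 2 libraries in each group, and adjusted p-values come from edgeR's quasi-likelihood test. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between libraries. That spread was pooled over the 6 groups, so it can be too small for Sdc1_KO, whose 2 libraries differed most. WT replicate 1 has a library number apart from those of the other 11 libraries, which run in sequence. The first 3 principal components of log2 CPM held 59.5%, 17.2% and 8.9% of the variance. On the first, Sdc1_KO lay at -8.1 and -13.3, between WT and Jhd2_KO (-35.1 to -39.1) and the other 3 groups. The 2 Sdc1_KO libraries differed most within a group, with a standard deviation of 0.429 for the log2 difference over genes against 0.247 to 0.296 in the other 5 groups.

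SDC1 (YDR469W, chromosome IV, 1399015 to 1399542) and JHD2 (YJR119C, chromosome X, 644304 to 646490) followed the labels. SDC1 stood at 24.9 ± 0.915 CPM (SD, n = 2) in WT and at 0 fragments in both Sdc1_KO libraries, at least 133-fold lower. It was lower in Dpy30_KO (14.4 ± 0.124 CPM, log2 fold change -0.79 ± 0.12, adjusted p = 0.0002), where part of the gene is deleted. SDC1 was higher in Sdc1_mut (38.8 ± 0.534 CPM, 0.64 ± 0.11, adjusted p = 0.00054) and in Sdc1_mut_Jhd2_KO (45.4 ± 0.826 CPM, 0.87 ± 0.11, adjusted p = 4.1e-05). JHD2 stood at 5.31 ± 1.36 CPM in WT and at 0 fragments in all libraries of Jhd2_KO (at least 17.9-fold lower) and Sdc1_mut_Jhd2_KO (at least 24.9-fold lower). JHD2 rose in all 3 single SDC1 mutants, by 1.54 ± 0.20 in Sdc1_KO (15.6 ± 2.03 CPM, adjusted p = 0.00016), 1.46 ± 0.21 in Dpy30_KO (adjusted p = 0.00021) and 1.35 ± 0.21 in Sdc1_mut (adjusted p = 0.00035).

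Fragments of mitochondrially encoded RNAs were nearly absent from 3 groups. They numbered 35130 to 62789 per library in WT, 48224 to 53235 in Sdc1_KO and 29213 to 37871 in Jhd2_KO. Dpy30_KO libraries held 8 to 17, Sdc1_mut libraries 2 to 9 and Sdc1_mut_Jhd2_KO libraries 9 to 16. This split runs between Sdc1_KO and the other SDC1 mutants, so it accompanies every difference between those groups.

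**Figure D1:**
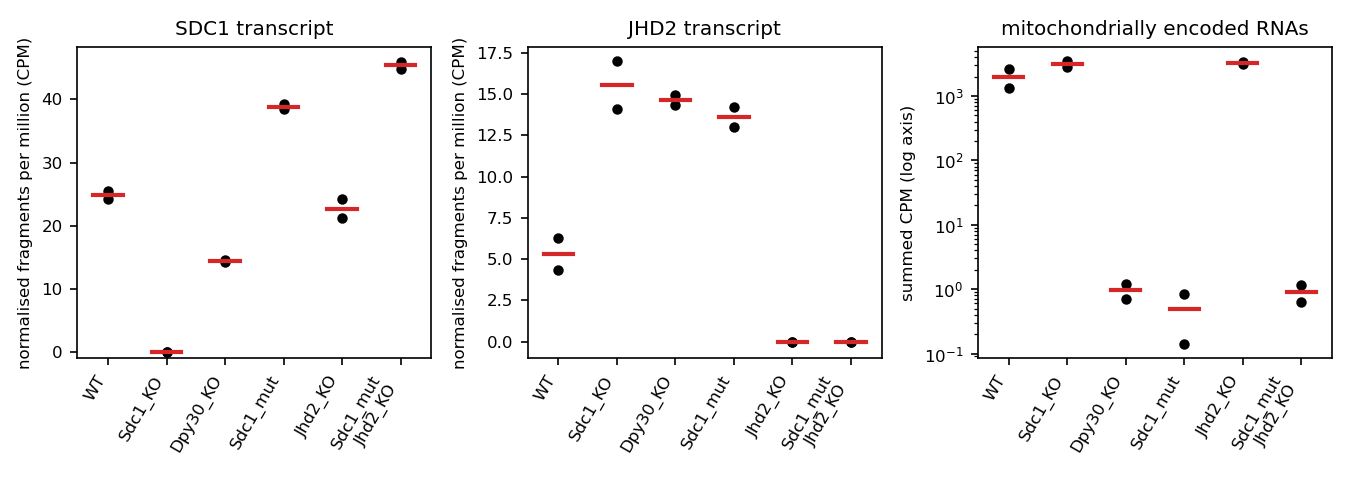
SDC1 transcript, JHD2 transcript and the sum of mitochondrially encoded RNAs in each of the 12 libraries, in TMM-scaled CPM (linear axes for the genes, a log axis for the mitochondrial sum). Black points are libraries and red bars the mean of each group of 2. SDC1 is at 0 in Sdc1_KO, JHD2 is at 0 in both groups with the JHD2 deletion, and mitochondrially encoded RNA is near 1 CPM or lower in Dpy30_KO, Sdc1_mut and Sdc1_mut_Jhd2_KO.

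In Sdc1_KO many, but not all, genes of purine biosynthesis, of meiosis and sporulation and of ribosome biogenesis rose. None of these list calls held with an estimated correlation. The largest rises against WT were those of ADE17, a purine biosynthesis enzyme (3.82 ± 0.29, adjusted p = 2e-06), and RSA4, a ribosome assembly factor (3.57 ± 0.29, adjusted p = 3.2e-06). MTD1, a one-carbon enzyme, rose by 2.81 ± 0.22 and SER3, a serine biosynthesis enzyme, by 2.73 ± 0.43. Genes known from sporulation followed: LOH1 (2.76 ± 0.18), PES4 (2.72 ± 0.21), the chitin deacetylase gene CDA1 (2.61 ± 0.25) and the kinase gene SPS1 (2.60 ± 0.22). ADF1 (2.64 ± 0.13, uncertain because it overlaps FYV5) and DAN1, a cell wall gene of anaerobic growth (2.59 ± 0.43), completed the 10. After SDC1 itself, the largest falls were those of the catalase gene CTT1 (-1.83 ± 0.37, adjusted p = 0.0013), the pyrimidine gene URA1 (-1.75 ± 0.13) and the eisosome gene NCE102 (-1.73 ± 0.21). They were followed by LSR1, the U2 spliceosomal RNA (-1.67 ± 0.20), YBL029C-A (-1.66 ± 0.19), VHS1 (-1.61 ± 0.27), AIM17 (-1.59 ± 0.22), the phosphoglucomutase gene PGM2 (-1.52 ± 0.21) and TDA1 (-1.42 ± 0.23). In the Set1 complex, SET1 rose by 0.59 ± 0.08 (adjusted p = 0.0001), BRE2 by 0.54 ± 0.11 and SWD3 by 0.47 ± 0.13 (adjusted p = 0.0097). The call of SWD3 ended without WT replicate 1 (adjusted p = 0.086) or Sdc1_KO replicate 1 (adjusted p = 0.091). TLG1, the neighbour of SDC1, fell by 0.93 ± 0.10 (adjusted p = 1.5e-05). Some of these values rested on 1 library, although the calls did not end: without Sdc1_KO replicate 1, SER3 stood at 1.39 and CTT1 at -1.23. Without Sdc1_KO replicate 2, SER3 stood at 3.41, DAN1 at 1.66, CTT1 at -2.95, VHS1 at -2.29 and TDA1 at -2.02.

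In Sdc1_KO 3208 of 6361 genes changed, 1782 higher and 1426 lower, 644 of them by at least 2-fold, and 10 of 41 gene lists were called (6 higher, 4 lower). The balance was 1399 higher and 1674 lower with limma-trend, and a fit of only these groups called 2036 genes. Genes of the translation machinery rose together: 110 of 134 cytosolic ribosomal protein genes rose and 1 fell (111 and 1 adjusted over the list alone, median 0.60, camera adjusted p = 5.6e-14, adjusted p = 0.8 with an estimated correlation). Their paralogs could part, as RPS14A rose (1.35 ± 0.12) and RPS14B fell (-1.29 ± 0.12). Ribosome biogenesis genes rose in 48 of 56 cases (50 adjusted over the list alone, with 1 lower, median 0.95, camera adjusted p = 1.4e-12, adjusted p = 0.57 with an estimated correlation), with NSR1 at 2.08 ± 0.13 and PWP2 at 2.13 ± 0.17. Purine genes rose in 12 of 19 cases (12 adjusted over the list alone, median 1.24, camera adjusted p = 8.5e-05, adjusted p = 0.74 with an estimated correlation), ADE1 by 1.97 ± 0.18. Meiosis and sporulation genes rose in 27 of 44 cases and fell in 4 (28 and 4 adjusted over the list alone, median 0.78, camera adjusted p = 0.00038, adjusted p = 0.57 with an estimated correlation). SPS19, which acts in fatty acid oxidation of sporulating cells, rose by 1.75 ± 0.10 and SPS22 by 2.09 ± 0.15. All 8 core histone genes fell (8 adjusted over the list alone, median -0.88, camera adjusted p = 0.0009, adjusted p = 0.74 with an estimated correlation), including HTA1 (-1.34 ± 0.23, or -1.94 without Sdc1_KO replicate 2). The iron regulon was not called in Sdc1_KO (5 of 23 genes rose and 7 fell, median -0.01, camera adjusted p = 0.54), but FIT1 (1.68 ± 0.17, adjusted p = 1.1e-05) and SIT1 (1.06 ± 0.13, adjusted p = 4.9e-05) rose.

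Nuclear genes of respiration fell in Sdc1_KO, which kept its mitochondrial transcripts. Of 43 genes of the respiratory chain and TCA cycle, 28 fell and 1 rose (31 and 2 adjusted over the list alone, median -0.52, camera adjusted p = 2.9e-09, adjusted p = 0.57 with an estimated correlation), with cytochrome genes CYT1 at -1.20 ± 0.13 and CYC1 at -1.02 ± 0.12. Mitochondrial ribosomal protein genes fell in 27 of 67 cases and rose in 2 (27 and 2 adjusted over the list alone, median -0.26, camera adjusted p = 8.5e-05, adjusted p = 0.8 with an estimated correlation). Stress-induced genes fell in 29 of 48 cases and rose in 2 (31 and 2 adjusted over the list alone, median -0.59, camera adjusted p = 9.6e-06, adjusted p = 0.8 with an estimated correlation). Thiamine and vitamin B6 genes rose in 12 of 23 cases and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.57 with an estimated correlation), led by SNZ1 (1.63 ± 0.12), and this call ended without Sdc1_KO replicate 1 (adjusted p = 0.11). G1 and S phase genes rose in 16 of 35 cases (16 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.57 with an estimated correlation), a call that ended without Sdc1_KO replicate 2 (adjusted p = 0.052). None of the list calls of any comparison held with an estimated correlation.

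In Dpy30_KO genes of iron uptake were higher than in WT, beside the near absence of mitochondrially encoded RNA. Against WT the cell wall genes FIT2 (4.88 ± 0.18, adjusted p = 3.1e-09), FIT3 (4.39 ± 0.16) and FIT1 (3.61 ± 0.16), which help retain iron, and the siderophore transporter gene SIT1 (3.65 ± 0.13) were among the 10 largest rises. So were the formate dehydrogenase genes FDH2 (5.30 ± 0.47) and FDH1 (4.85 ± 0.33), uncertain because they are near-identical copies. FDH2 stood at 4.52 without WT replicate 1 and at 6.85 without WT replicate 2. The others were HUG1, a DNA damage-induced regulator of ribonucleotide reductase (3.74 ± 0.32), LOH1 (3.52 ± 0.18), PES4 (3.48 ± 0.21) and the kinase gene RCK1 (3.33 ± 0.22). The 10 largest falls were all of mitochondrially encoded RNAs, such as OLI1. Chosen after the values were seen, the largest nuclear falls were those of the cell wall gene TIR1 (-3.55 ± 0.44), the heme biosynthesis gene HEM13 (-2.95 ± 0.21), the leucine biosynthesis genes LEU2 (-2.92 ± 0.14) and LEU1 (-2.76 ± 0.15), IZH4 (-2.85 ± 0.30) and the succinate dehydrogenase gene SDH1 (-2.67 ± 0.19). SET1 rose by 0.47 ± 0.08 (adjusted p = 0.00042) and BRE2 by 0.65 ± 0.11 (adjusted p = 0.00031). Of the neighbours of SDC1, UGO1 fell by 0.78 ± 0.11 (adjusted p = 0.0001), while TLG1 had a log2 fold change of -0.07 (adjusted p = 0.54).

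In Dpy30_KO 3330 genes changed, 1731 higher and 1599 lower, 784 of them by at least 2-fold, and with limma-trend 47.1% of the calls were higher. Of 41 lists 15 were called (8 higher, 7 lower). Nuclear respiratory genes fell in 41 of 43 cases and rose in 1 (41 and 1 adjusted over the list alone, median -1.38, camera adjusted p = 1.6e-19, adjusted p = 0.35 with an estimated correlation), in libraries with 8 to 17 mitochondrially encoded fragments. RIP1 fell by 2.11 ± 0.10 and COX4 by 2.10 ± 0.12. Iron regulon genes rose in 17 of 23 cases and fell in 2 (17 and 2 adjusted over the list alone, median 1.06, camera adjusted p = 9.1e-06, adjusted p = 0.35 with an estimated correlation), in the same libraries. Ribosome biogenesis genes rose in 55 of 56 cases (55 adjusted over the list alone, median 1.13, camera adjusted p = 3.3e-17, adjusted p = 0.35 with an estimated correlation). Cytosolic ribosomal protein genes rose in 115 of 134 cases and fell in 1 (118 and 1 adjusted over the list alone, median 0.63, camera adjusted p = 8.9e-16, adjusted p = 0.61 with an estimated correlation). Meiosis and sporulation genes rose in 27 of 44 cases and fell in 3 (27 and 3 adjusted over the list alone, median 0.93, camera adjusted p = 1.7e-05, adjusted p = 0.35 with an estimated correlation), SPS1 by 3.13 ± 0.22 and SPO74 by 3.16 ± 0.25. All 8 core histone genes fell again (8 adjusted over the list alone, median -0.94, camera adjusted p = 0.0016, adjusted p = 0.61 with an estimated correlation).

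Mating genes fell in Dpy30_KO: 6 of 7 a-specific genes (6 adjusted over the list alone, median -1.43, camera adjusted p = 0.0021, adjusted p = 0.35 with an estimated correlation), including the pheromone receptor gene STE2 (-1.43 ± 0.15) and the protease gene BAR1 (-1.57 ± 0.22). Of 25 haploid-specific and pheromone response genes, 12 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.61 with an estimated correlation), such as SST2 (-1.36 ± 0.10). Proteasome genes fell in 16 of 33 cases (16 adjusted over the list alone, camera adjusted p = 0.00017, adjusted p = 0.68 with an estimated correlation). Gcn4 targets of amino acid biosynthesis fell in 21 of 43 cases and rose in 11 (23 and 12 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.61 with an estimated correlation), with BAT1 at -1.99 ± 0.12 and ILV3 at -2.02 ± 0.14. Stress-induced genes fell in 21 of 48 cases and rose in 5 (21 and 5 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.74 with an estimated correlation). Hexose transporter genes rose in 10 of 15 cases and fell in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.35 with an estimated correlation), HXT3 by 1.77 ± 0.13 and HXT10 by 3.08 ± 0.21. Thiamine genes rose in 10 of 23 cases (10 adjusted over the list alone, camera adjusted p = 0.0021, adjusted p = 0.35 with an estimated correlation).

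Many of these changes were called in the point mutant too, again with 2 to 9 mitochondrially encoded fragments per library. FIT2 (4.61 ± 0.18, adjusted p = 5.8e-09), FIT3 (4.15 ± 0.16), SIT1 (3.74 ± 0.13) and FIT1 (3.50 ± 0.16) were among the 10 largest rises of Sdc1_mut against WT. The others were FDH1 (4.20 ± 0.34, uncertain as a near copy of FDH2), the lipid droplet gene LDS1 (3.67 ± 0.34), the exporter gene AQR1 (3.66 ± 0.20), HUG1 (3.38 ± 0.32), RSA4 (3.34 ± 0.29) and LOH1 (3.25 ± 0.18). All of the 10 largest falls were again of mitochondrially encoded RNAs. Among nuclear genes, chosen after the values were seen, TIR1 (-3.89 ± 0.45), HEM13 (-2.86 ± 0.21), LEU2 (-2.79 ± 0.14), SDH1 (-2.76 ± 0.19), IZH4 (-2.76 ± 0.30) and LEU1 (-2.56 ± 0.15) fell most. SET1 rose by 0.53 ± 0.08 (adjusted p = 0.00018) and BRE2 by 0.67 ± 0.11 (adjusted p = 0.00023). Both neighbours of SDC1 fell, TLG1 by 0.66 ± 0.10 and UGO1 by 0.50.

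In Sdc1_mut 3342 genes changed, 1773 higher and 1569 lower, 791 of them by at least 2-fold, and with limma-trend 45.6% of the calls were higher. Of 41 lists 13 were called (7 higher, 6 lower). Ribosome biogenesis genes rose in 55 of 56 cases (55 adjusted over the list alone, median 1.38, camera adjusted p = 1.7e-20, adjusted p = 0.46 with an estimated correlation), NSR1 by 2.42 ± 0.14. Cytosolic ribosomal protein genes rose in 122 of 134 cases (122 adjusted over the list alone, median 0.71, camera adjusted p = 7e-19, adjusted p = 0.7 with an estimated correlation). Nuclear respiratory genes fell in 41 of 43 cases and rose in 1 (41 and 1 adjusted over the list alone, median -1.25, camera adjusted p = 1.7e-20, adjusted p = 0.46 with an estimated correlation), and iron regulon genes rose in 17 of 23 cases and fell in 2 (17 and 2 adjusted over the list alone, median 1.18, camera adjusted p = 8.9e-06, adjusted p = 0.46 with an estimated correlation). Meiosis and sporulation genes rose in 23 of 44 cases and fell in 3 (23 and 3 adjusted over the list alone, median 0.78, camera adjusted p = 0.00025, adjusted p = 0.46 with an estimated correlation). All 8 histone genes fell (8 adjusted over the list alone, median -0.83, camera adjusted p = 0.0026, adjusted p = 0.7 with an estimated correlation), as did 20 of 33 proteasome genes (20 adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.72 with an estimated correlation). Of the 7 a-specific genes 6 fell (6 adjusted over the list alone, camera adjusted p = 0.0089, adjusted p = 0.46 with an estimated correlation), ASG7 by 1.51 ± 0.22, in the libraries that lacked mitochondrial transcripts. Stress-induced genes fell in 25 of 48 cases and rose in 5 (25 and 5 adjusted over the list alone, camera adjusted p = 0.0029, adjusted p = 0.78 with an estimated correlation).

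The 3 SDC1 mutants shared many of their changes. In the same direction in all 3, 1171 genes rose and 915 fell, 2086 together. The balance turned with limma-trend, to 933 higher and 1064 lower. Among them were all 8 core histone genes (lower), 101 of 134 cytosolic ribosomal protein genes and 48 of 56 ribosome biogenesis genes (higher), 28 of 43 respiratory genes (lower) and 22 of 44 meiosis and sporulation genes (higher). BNA4 and BNA2, genes of NAD biosynthesis from tryptophan, rose in each: BNA4 by 1.98 ± 0.10 in Sdc1_KO, 1.98 ± 0.10 in Dpy30_KO and 2.19 ± 0.10 in Sdc1_mut, and BNA2 by 1.87 ± 0.20, 2.46 ± 0.20 and 2.34 ± 0.20. Sdc1_KO and Sdc1_mut shared 2310 calls of the same direction against 848 for independent lists, and 87 were opposite. Dpy30_KO and Sdc1_mut shared 2905 against 877, and 1 was opposite. Fold changes over genes, mitochondrially encoded RNAs included, correlated at r = 0.56 for Sdc1_KO and Sdc1_mut and at r = 0.96 for Dpy30_KO and Sdc1_mut. Large falls of these RNAs, such as AI2 (-12.94 in Dpy30_KO and -12.06 in Sdc1_mut), enter r and the covariances given below. Neither was computed without them. Dpy30_KO and Sdc1_mut both nearly lacked mitochondrially encoded fragments (8 to 17 and 2 to 9 per library), unlike Sdc1_KO (48224 to 53235). Their closer agreement cannot be told apart from this shared state. All comparisons share the same 2 WT libraries: in 50 simulations with no effect the mean r was 0.43 and 0.41, but at most 1 call was shared. Few genes are called where there is no effect, so this does not show how far the shared libraries add to the shared calls. The covariances were 0.362 and 0.857, against 0.0221 in the simulations of either pair. Genes are not independent replicates.

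**Figure D2:**
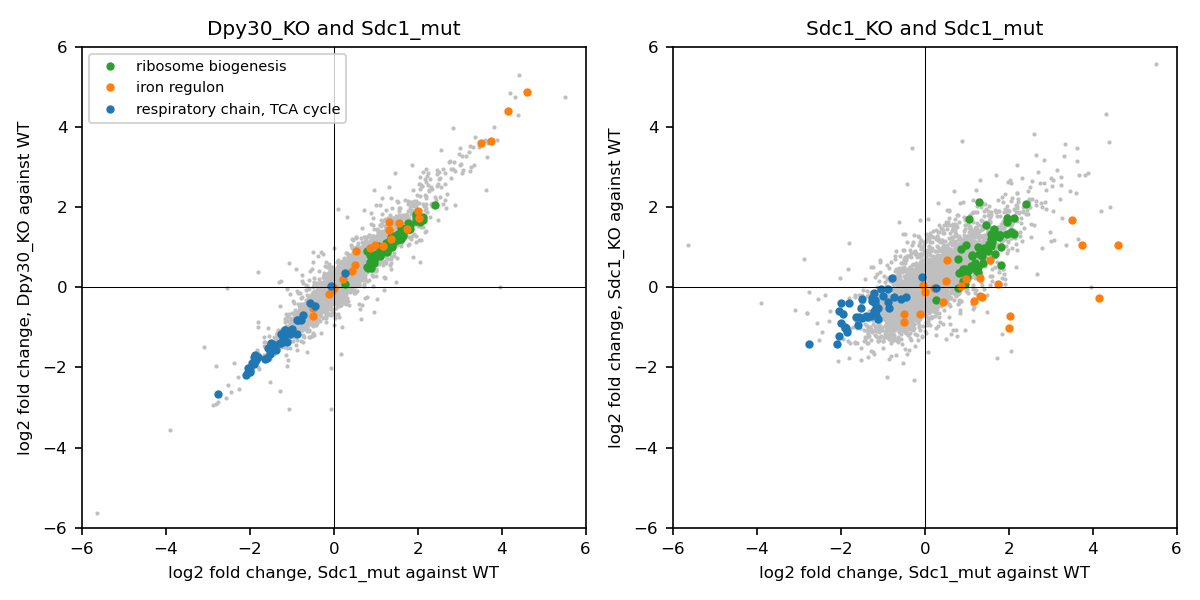
Log2 fold changes against WT in Dpy30_KO (left) and Sdc1_KO (right), each plotted against those in Sdc1_mut. Each point is a gene, and genes of 3 lists are coloured. Dpy30_KO lies along the diagonal (r = 0.96), while in Sdc1_KO (r = 0.56) iron regulon genes scatter on both sides of 0 (median -0.01) and respiratory genes fall less (median -0.52 against -1.25 in Sdc1_mut). Values beyond 6 either way, mostly of mitochondrially encoded RNAs, lie outside the axes but enter r.

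The direct comparison of Dpy30_KO with Sdc1_mut called 1 gene, SDC1 itself (-1.43 ± 0.12, adjusted p = 0.00047). DESeq2 called 3 genes, limma-trend 1 and a fit of only these groups 17, and 437 genes had an unadjusted p under 0.05. Leaving out Dpy30_KO replicate 1 gave 2 genes. Small shifts of whole lists separated these 2 groups by camera: 15 of 41 lists were called, 10 higher and 5 lower in Dpy30_KO, with list medians of at most 0.31 either way. With an estimated correlation 0 were called, the fry test called 1 of the 15, and 7 stayed called in all 4 fits without 1 library (10 without Dpy30_KO replicate 1, 8 without Sdc1_mut replicate 2). Ribosome biogenesis genes had the lowest camera p, shifted downward with 0 of 56 genes called (0 adjusted over the list alone, median -0.25, camera adjusted p = 4.6e-13, adjusted p = 0.37 with an estimated correlation). The gene deletion differed from both other alleles. Against Sdc1_mut, Sdc1_KO differed in 1360 genes, 719 higher and 641 lower, and against Dpy30_KO in 1603, 890 higher and 713 lower. Lists called numbered 16 of 41 against Sdc1_mut (8 higher, 8 lower) and 18 against Dpy30_KO (7 higher, 11 lower), of which 8 and 10 stayed called in every fit without 1 library (11 and 12 without Sdc1_KO replicate 1). Fits of only the groups compared called 454 and 500 genes. The balance turned with limma-trend, to 612 higher and 622 lower against Sdc1_mut and 766 higher and 774 lower against Dpy30_KO. Among nuclear genes, HEM13 (3.58 ± 0.21), TIR1 (3.49 ± 0.45), DAN1 (3.02 ± 0.49), IZH4 (2.65 ± 0.30) and ANB1 (2.28 ± 0.21) were most above Sdc1_mut, and they were added after the values were seen. After SDC1 itself, FIT3 (-4.42 ± 0.16), FIT2 (-3.55 ± 0.17), URA1 (-3.46 ± 0.14) and TIS11, an iron-responsive RNA-binding factor (-3.03 ± 0.14), were most below it. Against Dpy30_KO, HEM13 was higher by 3.66 ± 0.21 and TIR1 by 3.15 ± 0.44, while SDC1 itself, FIT3 (-4.66 ± 0.16), FIT2 (-3.82 ± 0.17) and URA1 (-3.48 ± 0.14) were lower. Mitochondrially encoded RNAs gave the 5 largest rises in both comparisons. Without Sdc1_KO replicate 2 the balance turned too, to 942 higher and 1200 lower against Sdc1_mut and 1037 higher and 1199 lower against Dpy30_KO. The count against Sdc1_mut was 2142 without Sdc1_KO replicate 2, 646 without Sdc1_mut replicate 1 and 671 without Sdc1_mut replicate 2. The count against Dpy30_KO was 804 without Dpy30_KO replicate 1 and 978 without Dpy30_KO replicate 2. Without Sdc1_KO replicate 1, TIR1 stood at 4.15 against Sdc1_mut and 3.81 against Dpy30_KO. Without Sdc1_KO replicate 2, TIR1 stood at 2.21 and 1.87, and against Sdc1_mut DAN1 stood at 2.10 and IZH4 at 2.05.

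Fewer genes differed between Jhd2_KO and WT. Rises led by SEO1, a permease gene (1.45 ± 0.15, adjusted p = 0.00066), BNA4 (1.15 ± 0.10, adjusted p = 0.00024), the S-adenosylmethionine synthetase gene SAM2 (0.96 ± 0.11, adjusted p = 0.0012) and SPS19 (0.95 ± 0.10, adjusted p = 0.00066) stayed called without any of the 4 libraries. The other large rises were MIP6 (1.26 ± 0.24), FMO1 (1.10 ± 0.19), the inositol synthesis gene INO1 (1.06 ± 0.21), YKR005C (0.94 ± 0.16), STR3 (0.89 ± 0.13) and YHR137C-A (0.87 ± 0.19, an identifier outside the annotation, not checked for copies or overlaps). The largest falls were mostly of ribosome assembly genes: DHR2 (-1.49 ± 0.31, adjusted p = 0.036), IMP3 (-1.36 ± 0.22), BMT5 (-1.01 ± 0.21), PUF6 (-0.93 ± 0.18), NOG2 (-0.92 ± 0.20, uncertain because it holds snR191) and HCA4 (-0.90 ± 0.13), beside TOD6, a repressor of such genes (-1.32 ± 0.25), AIF1 (-1.03 ± 0.22) and TRM11 (-0.91 ± 0.16). ILM1, the neighbour of JHD2, fell by 1.05 ± 0.16 (adjusted p = 0.011), a call that ended without WT replicate 2 (adjusted p = 0.083), Jhd2_KO replicate 1 (0.11) or Jhd2_KO replicate 2 (0.12). Of these 20 genes, 9 stayed called without WT replicate 1, 4 without WT replicate 2, 4 without Jhd2_KO replicate 1 and 6 without Jhd2_KO replicate 2. No gene of the Set1 complex was called, SET1 standing at 0.07 ± 0.08 (adjusted p = 0.72).

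In Jhd2_KO 104 genes changed, 48 higher and 56 lower, 16 of them by at least 2-fold, while 17 of 41 lists were called (13 higher, 4 lower). The count was 26 without WT replicate 1 (5 higher, 21 lower), 15 without WT replicate 2 (11 higher, 4 lower), 5 without Jhd2_KO replicate 1 (4 higher, 1 lower) and 11 without Jhd2_KO replicate 2 (6 higher, 5 lower), so the balance rested on single libraries. It was 271 with DESeq2, 53 with limma-trend and 623 in a fit of only these groups. Ribosome biogenesis genes fell in 10 of 56 cases (34 adjusted over the list alone, median -0.48, camera adjusted p = 4.9e-20, adjusted p = 0.38 with an estimated correlation), as UTP5 (-0.84 ± 0.10, adjusted p = 0.0012, or 0.058 without Jhd2_KO replicate 1). Methionine and sulfur genes rose in 5 of 27 cases (16 adjusted over the list alone, median 0.66, camera adjusted p = 7.2e-12, adjusted p = 0.47 with an estimated correlation). Meiosis and sporulation genes rose in 5 of 44 cases (14 adjusted over the list alone, with 2 lower, median 0.41, camera adjusted p = 1.2e-08, adjusted p = 0.35 with an estimated correlation). NAD biosynthesis genes rose in 2 of 13 cases (3 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.35 with an estimated correlation) and thiamine genes in 1 of 23 (6 adjusted over the list alone, camera adjusted p = 0.00045, adjusted p = 0.35 with an estimated correlation). Ergosterol genes shifted upward with 0 of 24 called (0 adjusted over the list alone, median 0.19, camera adjusted p = 6e-06, adjusted p = 0.35 with an estimated correlation). Cytosolic ribosomal protein genes shifted downward with 1 of 134 called (1 adjusted over the list alone, median -0.16, camera adjusted p = 3.4e-07, adjusted p = 0.72 with an estimated correlation), but not without WT replicate 2 (adjusted p = 0.6). Of the 104 genes, 38 were called in the same direction in Sdc1_mut and 50 in the opposite direction, against 27 for independent lists either way. These comparisons share the WT libraries. In 50 simulations with no effect 0 calls were shared either way, but with few genes called there this does not show how far sharing adds to the counts. Over genes r was 0.05 against a simulated 0.38 (covariance 0.0173 against 0.0216).

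Respiratory and iron genes shifted in Jhd2_KO against the direction of Sdc1_mut. Nuclear respiratory genes shifted upward with 0 of 43 called (0 adjusted over the list alone, median 0.09, camera adjusted p = 0.0065, adjusted p = 0.72 with an estimated correlation), but not without Jhd2_KO replicate 1 (adjusted p = 0.16). Iron regulon genes shifted downward with 1 of 23 called (4 adjusted over the list alone, median -0.14, camera adjusted p = 0.016, adjusted p = 0.72 with an estimated correlation), but not without WT replicate 1 (adjusted p = 0.11). Core histone genes shifted downward, as in the SDC1 mutants, with 0 of 8 called (1 adjusted over the list alone, median -0.25, camera adjusted p = 0.014, adjusted p = 0.72 with an estimated correlation), but not without WT replicate 2 (adjusted p = 0.11) or Jhd2_KO replicate 1 (0.067). Stress-induced genes rose in 4 of 48 cases (5 adjusted over the list alone, median 0.11, camera adjusted p = 0.016, adjusted p = 0.76 with an estimated correlation), but the list was not called without WT replicate 2 (adjusted p = 0.11) or Jhd2_KO replicate 1 (0.073). Upward shifts with 0 genes called were those of 67 mitochondrial ribosomal protein genes (6 adjusted over the list alone, median 0.15, camera adjusted p = 5.7e-05, adjusted p = 0.72 with an estimated correlation) and 33 proteasome genes (0 adjusted over the list alone, median 0.14, camera adjusted p = 0.002, adjusted p = 0.72 with an estimated correlation).

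The strain with both the point mutation and the JHD2 deletion had the most changes against WT: 3768 genes, 1851 higher and 1917 lower, 1026 of them by at least 2-fold, and 15 of 41 lists (10 higher, 5 lower). Its libraries held 9 to 16 mitochondrially encoded fragments. The largest rises were those of the spore wall gene OSW1 (4.17 ± 0.33, adjusted p = 7.8e-07), FIT2 (4.08 ± 0.18), FRM2 (4.08 ± 0.30), the biotin synthesis gene BIO4 (4.01 ± 0.17) and YOR338W (3.87 ± 0.23). OSW1 stood at 4.98 without WT replicate 2. FIT3 (3.78 ± 0.15), the thiamine synthesis gene THI4 (3.73 ± 0.28), the gluconeogenesis gene PCK1 (3.62 ± 0.17), AQR1 (3.61 ± 0.20) and SPO74 (3.61 ± 0.25) followed. Mitochondrially encoded RNAs again gave the 10 largest falls. Among nuclear genes, chosen after the values were seen, TIR1 (-4.49 ± 0.47), the serine deaminase gene CHA1 (-3.58 ± 0.58), the guanine nucleotide gene IMD2 (-3.53 ± 0.24), IZH4 (-3.40 ± 0.31), HEM13 (-3.16 ± 0.21) and RPR1, the RNA of RNase P (-2.91 ± 0.13), fell most. SET1 rose by 0.55 ± 0.08, BRE2 rose by 0.64 ± 0.11 and SWD2 fell by 0.83 ± 0.14 (adjusted p = 0.00022).

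In Sdc1_mut_Jhd2_KO nuclear respiratory genes fell in 42 of 43 cases (42 adjusted over the list alone, with 1 higher, median -1.41, camera adjusted p = 1.4e-17, adjusted p = 0.36 with an estimated correlation), and iron regulon genes rose in 16 of 23 cases and fell in 3 (17 and 3 adjusted over the list alone, median 1.26, camera adjusted p = 8.3e-06, adjusted p = 0.36 with an estimated correlation), beside the missing mitochondrial transcripts. Ribosome biogenesis genes rose in 52 of 56 cases (52 adjusted over the list alone, median 0.93, camera adjusted p = 4.3e-13, adjusted p = 0.46 with an estimated correlation). Meiosis and sporulation genes rose in 31 of 44 cases and fell in 2 (31 and 3 adjusted over the list alone, median 1.15, camera adjusted p = 3e-06, adjusted p = 0.36 with an estimated correlation). Proteasome genes fell in 29 of 33 cases and rose in 1 (30 and 1 adjusted over the list alone, median -0.74, camera adjusted p = 1.4e-08, adjusted p = 0.51 with an estimated correlation). All 8 histone genes fell (8 adjusted over the list alone, median -1.42, camera adjusted p = 0.00016, adjusted p = 0.51 with an estimated correlation), HTA2 by 1.91 ± 0.15. Mitochondrial ribosomal protein genes fell in 36 of 67 cases and rose in 4 (38 and 4 adjusted over the list alone, camera adjusted p = 8.3e-05, adjusted p = 0.66 with an estimated correlation). Chaperone genes rose in 10 of 16 cases and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.66 with an estimated correlation), a call that ended without WT replicate 1 or Sdc1_mut_Jhd2_KO replicate 2 (adjusted p = 0.059 each). Multidrug and Pdr genes rose in 10 of 16 cases (10 adjusted over the list alone, camera adjusted p = 0.0091, adjusted p = 0.36 with an estimated correlation).

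Compared with Sdc1_mut, the strain that differs by the JHD2 deletion, some stress-induced genes rose and most ribosomal protein genes fell in Sdc1_mut_Jhd2_KO. Neither list call held with an estimated correlation. The largest rises were those of the stationary-phase gene SPG4 (3.07 ± 0.33, adjusted p = 5.4e-05), the small heat shock protein gene HSP26 (2.89 ± 0.32), SLZ1 (2.72 ± 0.25), YHR033W (2.71 ± 0.25) and BTN2 (2.55 ± 0.47). Besides JHD2, the largest falls were those of YIR042C (-2.47 ± 0.59, adjusted p = 0.0072) and CHA1 (-1.95 ± 0.60, adjusted p = 0.025). RPR1 (-1.93 ± 0.13) and URA1 (-1.74 ± 0.13) followed. URA1 stood at 867.4 CPM in Sdc1_mut, 260.1 in Sdc1_mut_Jhd2_KO and 264.6 in WT. CHA1 lost its call without any 1 of the 4 libraries: Sdc1_mut replicate 1 (adjusted p = 0.076) or 2 (0.086), Sdc1_mut_Jhd2_KO replicate 1 (0.16) or 2 (0.076). YIR042C lost it without Sdc1_mut replicate 2 (0.068), Sdc1_mut_Jhd2_KO replicate 1 (0.052) or 2 (0.057). In all 2069 genes changed, 838 higher and 1231 lower, and 1326 did without Sdc1_mut replicate 1, 1100 without Sdc1_mut replicate 2 and 1296 without Sdc1_mut_Jhd2_KO replicate 1. With limma-trend 51.5% of the calls were higher, against 40.5% here. Of 1773 genes higher in Sdc1_mut than in WT, 510 were lower in Sdc1_mut_Jhd2_KO than in Sdc1_mut (343 for independent lists) and 196 higher (234). Of 1569 lower ones, 263 were higher (207 for independent lists) and 239 lower (304). Both contrasts share the Sdc1_mut libraries. In 50 simulations with no effect of the second contrast each of these 4 counts was at most 1. Few genes can be called in that contrast then, so this does not show how far the shared libraries add to the counts. Over genes r was -0.12 against a simulated mean of -0.112. The simulated second contrast held noise alone, while the real one also held changed genes, so these values of r are not alike. They cannot tell whether there was a reversal beyond that from the shared libraries.

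Relative to Sdc1_mut 17 of 41 lists were called (10 higher, 7 lower). Cytosolic ribosomal protein genes fell in 111 of 134 cases (120 adjusted over the list alone, median -0.63, camera adjusted p = 5.6e-22, adjusted p = 0.52 with an estimated correlation), such as RPL12A (-0.99 ± 0.13) and RPS10A (-0.99 ± 0.13). Gcn4 targets of amino acid biosynthesis rose in 28 of 43 cases and fell in 1 (32 and 2 adjusted over the list alone, median 0.79, camera adjusted p = 7.7e-12, adjusted p = 0.41 with an estimated correlation), HOM2 by 1.24 ± 0.11 and HIS4 by 1.08 ± 0.12. Chaperone genes rose in 13 of 16 cases and fell in 1 (13 and 1 adjusted over the list alone, median 1.04, camera adjusted p = 1.7e-07, adjusted p = 0.46 with an estimated correlation), MDJ1 by 1.57 ± 0.13 and SSA3 by 1.39 ± 0.14. Stress-induced genes rose in 22 of 48 cases and fell in 1 (26 and 1 adjusted over the list alone, camera adjusted p = 1.7e-07, adjusted p = 0.53 with an estimated correlation). Glucose-repressed genes of carbon metabolism rose in 12 of 30 cases and fell in 3 (12 and 3 adjusted over the list alone, camera adjusted p = 0.0005, adjusted p = 0.46 with an estimated correlation), ACS1 by 2.39 ± 0.21. Ribosome biogenesis genes fell in 27 of 56 cases (28 adjusted over the list alone, with 1 higher, median -0.37, camera adjusted p = 9.4e-06, adjusted p = 0.53 with an estimated correlation). Proteasome genes fell in 19 of 33 cases and rose in 1 (25 and 1 adjusted over the list alone, camera adjusted p = 4.8e-06, adjusted p = 0.53 with an estimated correlation), while RPN4, the activator of these genes, rose by 1.09 ± 0.12. Core histone genes fell in 7 of 8 cases (7 adjusted over the list alone, median -0.66, camera adjusted p = 0.0027, adjusted p = 0.53 with an estimated correlation). Ergosterol genes fell in 11 of 24 cases (12 adjusted over the list alone, camera adjusted p = 0.0049, adjusted p = 0.46 with an estimated correlation) and G1 and S phase genes in 15 of 35, with 1 higher (16 and 1 adjusted over the list alone, camera adjusted p = 0.00035, adjusted p = 0.44 with an estimated correlation).

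**Figure D3:**
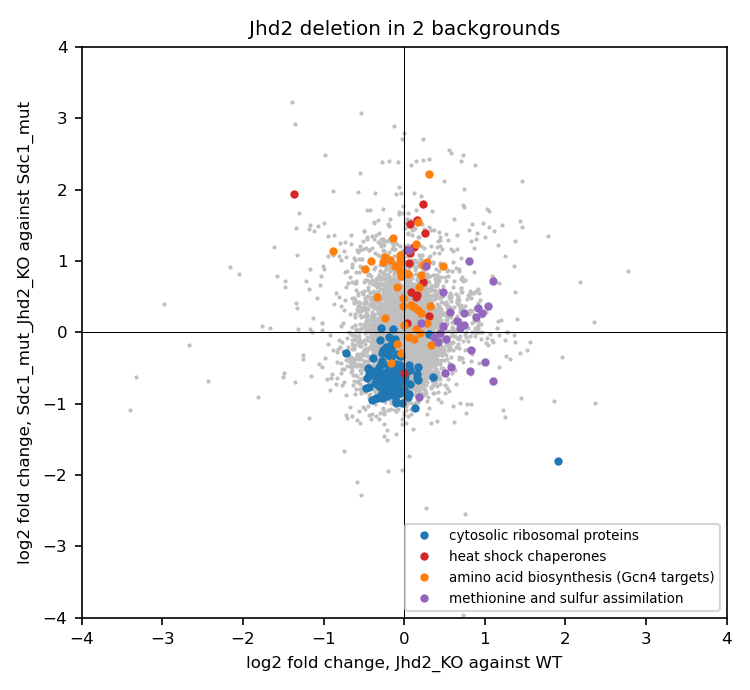
Log2 fold change of each gene in Jhd2_KO against WT (horizontal) and in Sdc1_mut_Jhd2_KO against Sdc1_mut (vertical). Each point is a gene, and genes of 4 lists are coloured. Ribosomal protein genes have a median of -0.16 across and -0.63 down, and chaperone genes a median of 1.04 on the vertical axis. JHD2, 15S_rRNA, YDR210W-A (uncertain because of near copies) and YPR108W-A (outside the annotation) lie outside the axes.

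Against Jhd2_KO, the strain that differs by the point mutation, 3716 genes changed in Sdc1_mut_Jhd2_KO, 1819 higher and 1897 lower, 1066 by at least 2-fold, and 14 of 41 lists were called (7 higher, 7 lower). YER137W-A (4.47 ± 0.30, outside the annotation and not checked for copies or overlaps), SPO74 (4.34 ± 0.31), FIT2 (4.03 ± 0.19), YMR244W (4.01 ± 0.29) and SPG4 (3.98 ± 0.35) rose most. SPO74 stood at 5.22 without Jhd2_KO replicate 1 and at 3.66 without Jhd2_KO replicate 2, and YMR244W at 5.05 without the latter. The 5 largest falls were of mitochondrially encoded RNAs, and the largest nuclear falls, added after the values were seen, were those of TIR1 (-4.83 ± 0.47), IMD2 (-3.61 ± 0.24) and CHA1 (-3.38 ± 0.59). Ribosome biogenesis genes rose in 55 of 56 cases (55 adjusted over the list alone, median 1.36, camera adjusted p = 8.2e-19, adjusted p = 0.51 with an estimated correlation), and respiratory genes fell in 42 of 43 (42 adjusted over the list alone, median -1.59, camera adjusted p = 8.2e-19, adjusted p = 0.51 with an estimated correlation). Iron regulon genes rose in 17 of 23 cases and fell in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 6.5e-07, adjusted p = 0.51 with an estimated correlation), again beside the missing mitochondrial transcripts. Methionine and sulfur genes fell in 15 of 27 cases and rose in 1 (15 and 1 adjusted over the list alone, median -0.68, camera adjusted p = 0.014, adjusted p = 0.8 with an estimated correlation), MET17 by 1.38 ± 0.17. All 8 core histone genes fell (8 adjusted over the list alone, median -1.19, camera adjusted p = 0.00098, adjusted p = 0.59 with an estimated correlation). Proteasome genes fell in 30 of 33 cases and rose in 1 (31 and 1 adjusted over the list alone, camera adjusted p = 7e-10, adjusted p = 0.58 with an estimated correlation), and cytosolic ribosomal protein genes rose in 48 of 134 and fell in 1 (42 and 0 adjusted over the list alone, camera adjusted p = 0.00047, adjusted p = 0.82 with an estimated correlation).

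Smaller groups of genes were each called in 1 to 3 of the 7 comparisons, and 1 comparison is given for each. Galactose genes and other subtelomeric genes were called in 3, alpha-specific genes in 2, and the COS, PAU, INO and phosphate lists in 1. Galactose genes rose in 4 of 7 cases in Sdc1_mut_Jhd2_KO relative to Sdc1_mut (5 adjusted over the list alone, median 0.44, camera adjusted p = 0.0031, adjusted p = 0.46 with an estimated correlation). Their calls in Sdc1_mut_Jhd2_KO against WT and against Jhd2_KO ended without WT replicate 2 (adjusted p = 0.068) and without Jhd2_KO replicate 2 (0.074) or Sdc1_mut_Jhd2_KO replicate 2 (0.059). Relative to Sdc1_mut also 7 of 27 other subtelomeric genes rose and 2 fell (7 and 2 adjusted over the list alone, median 0.38, camera adjusted p = 0.0063, adjusted p = 0.53 with an estimated correlation), and 3 of 9 COS genes rose (3 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.46 with an estimated correlation), uncertain because COS genes include near copies. The other subtelomeric calls ended in Jhd2_KO against WT without WT replicate 2 (adjusted p = 0.42) or Jhd2_KO replicate 2 (0.11), and in Sdc1_mut_Jhd2_KO against WT without WT replicate 2 (0.1) or Sdc1_mut_Jhd2_KO replicate 1 (0.087). In Dpy30_KO 5 of 11 seripauperin PAU genes, also near copies, rose against WT (4 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.35 with an estimated correlation), but not without Dpy30_KO replicate 2 (adjusted p = 0.053). In Sdc1_mut_Jhd2_KO 4 of 5 alpha-specific genes rose against WT (4 adjusted over the list alone, median 0.90, camera adjusted p = 0.042, adjusted p = 0.46 with an estimated correlation), a call that ended without WT replicate 1 (adjusted p = 0.059), Sdc1_mut_Jhd2_KO replicate 1 (0.052) or 2 (0.054). Their call in Jhd2_KO ended without Jhd2_KO replicate 1 (adjusted p = 0.26). In Jhd2_KO phospholipid INO genes shifted upward with 1 of 16 called (1 adjusted over the list alone, camera adjusted p = 0.0052, adjusted p = 0.7 with an estimated correlation), but not without Jhd2_KO replicate 2 (adjusted p = 0.06). Phosphate regulon genes did so with 0 of 17 called (1 adjusted over the list alone, camera adjusted p = 0.05, adjusted p = 0.47 with an estimated correlation), but not without WT replicate 2 (adjusted p = 0.27) or Jhd2_KO replicate 1 (0.13).

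**Figure D4:**
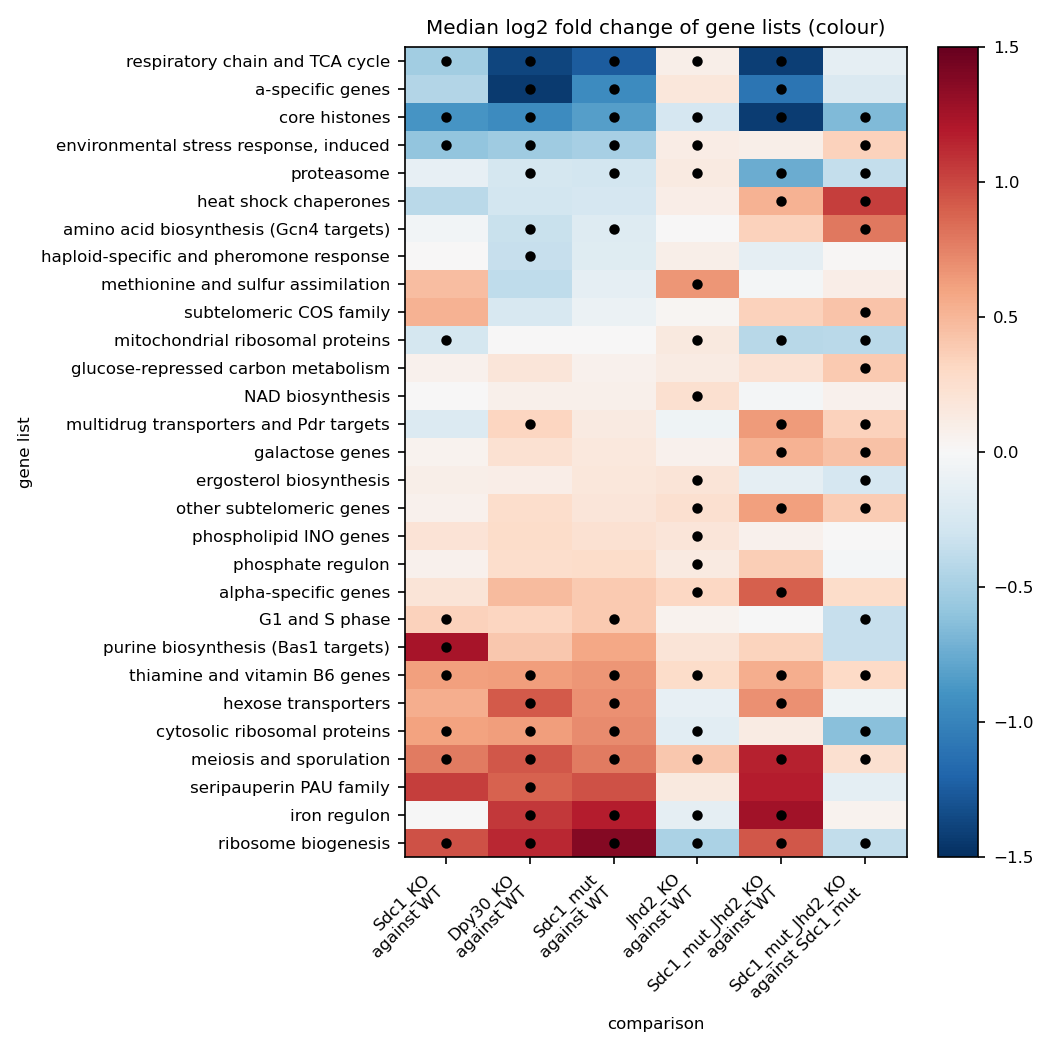
Median log2 fold change of the gene lists called in at least 1 of 7 comparisons (vertical) in 6 comparisons (horizontal), with colour clipped at 1.5 either way. A black dot marks a list called by camera with the preset correlation, and none of these calls held with an estimated correlation. Respiratory genes are lower in all 3 SDC1 mutants, and iron regulon genes are higher in Dpy30_KO (median 1.06) and Sdc1_mut (1.18) but not in Sdc1_KO (-0.01).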

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

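The tests of the library scaling and of the whole stress program were chosen only after the result was seen. The difference between strains without and with JHD2 was not the same in the point mutant as in WT by a test of this itself (the interaction in edgeR's quasi-likelihood test), in 1297 genes, 534 with a higher and 763 with a lower log2 change in the point mutant. The balance rested on the method: it was 638 higher and 484 lower with limma-trend, 592 and 620 with RLE factors, and 608 and 596 without identifiers outside the annotation (an alternative chosen after seeing the data). A fit of only these groups called 2130 genes. In part the 2 differences were alike: of 104 genes changed in Jhd2_KO against WT, 38 were called in the same direction in Sdc1_mut_Jhd2_KO against Sdc1_mut (17.2 for independent lists) and 12 in the opposite one (16.7), 70.2% had the same sign, and r over all genes was 0.10. Of 41 gene lists 13 were called (6 higher, 7 lower, 0 with an estimated correlation), and 9 of them stayed called in all 8 fits without 1 library. The largest positive differences were those of the stress genes SPG4 (3.61 ± 0.48, adjusted p = 0.00066), HSP30 (3.30 ± 0.68) and HSP26 (3.02 ± 0.43), and of YER137W-A (3.47 ± 0.41, outside the annotation and not checked for copies or overlaps) and YER137C (2.78 ± 0.45). The largest negative ones were those of YIR042C (-2.74 ± 0.75, adjusted p = 0.023), the permease gene SEO1 (-2.38 ± 0.22), the RNase P RNA RPR1 (-1.90 ± 0.17), the pyrimidine gene URA1 (-1.79 ± 0.18) and the ATP sulfurylase gene MET3 (-1.79 ± 0.37). YIR042C lost its call without WT replicate 1 (adjusted p = 0.08), Sdc1_mut replicate 2 (0.1), Jhd2_KO replicate 1 (0.066) or 2 (0.061), and Sdc1_mut_Jhd2_KO replicate 1 (0.079) or 2 (0.088). The number of genes was 634 without WT replicate 1, 785 and 617 without Sdc1_mut replicates 1 and 2, 580 without Jhd2_KO replicate 2, and 829 and 838 without Sdc1_mut_Jhd2_KO replicates 1 and 2.

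Among the 13 lists, 2 were picked for weighing after the calls were seen. The log2 change with the JHD2 deletion was lower in the point mutant than in WT for ribosomal protein genes (median interaction -0.49, camera adjusted p = 3.5e-10, or 0.81 with an estimated correlation). For chaperone genes this change was higher in the point mutant (median interaction 0.98, camera adjusted p = 1.5e-05, or 0.65 with an estimated correlation). A single library is argued against, as both lists stayed called in 8 of 8 fits that each left out 1 library. With RLE factors the medians were -0.45 for ribosomal protein genes and 1.02 for chaperone genes. Scaling shifts all genes of a library alike, so it cannot by itself move these 2 lists in opposite directions. TMM and RLE both rest on most genes being unchanged, and no spike-in was added. A scaling error common to both, and so the size of each shift, therefore stays open. A shift of the whole stress program stays open: the median of 0.13 for ribosome biogenesis genes cannot decide it, as these genes fell with the JHD2 deletion in WT too (median -0.48) and in 27 of 56 cases in the point mutant (median -0.37), where 22 of 48 stress-induced genes rose, and the bound for this test was changed after the 0.13 was seen. The contrast is also confounded with the near absence of mitochondrially encoded fragments from the Sdc1_mut (2 to 9) and Sdc1_mut_Jhd2_KO (9 to 16) libraries, and this, a further difference of the strains and how the cultures grew stay open and were not tested.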

How the results depend on the processing

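The alternative without identifiers outside the annotation was chosen after seeing the data. No named gene reversed under any alternative, and no call became an opposite call (0). Of the named values, DESeq2 kept 1132 of 1139 on their side of the threshold, limma-trend 1087 of 1139, RLE factors 1135 of 1139, no filter 1137 of 1139, the replicate block 1136 of 1139, only the groups compared 1108 of 1137, abundant RNAs left out 1093 of 1093, identifiers outside the annotation left out 1130 of 1136, and leaving out 1 library 4290 of 4632. Of 136 counts of changed genes under alternatives, 107 were within 1.5-fold, and the largest shift of the median of all genes was 0.08. The others were as follows, and the cause was not tested except that leaving out a library leaves fewer samples, the lone one being assumed to vary like the other groups. With only the groups compared the count was 2036 for Sdc1_KO against WT, 623 for Jhd2_KO, 454 for Sdc1_KO against Sdc1_mut, 500 against Dpy30_KO, 17 for Dpy30_KO against Sdc1_mut and 2130 for the interaction. DESeq2 gave 271 for Jhd2_KO and 3 for Dpy30_KO against Sdc1_mut, limma-trend 53 for Jhd2_KO and the replicate block 164. Replicate numbers did not pair libraries across groups (r of replicate differences -0.13 to 0.16 over 15 pairs of groups). Leaving out 1 library gave 5 to 26 genes for Jhd2_KO, 1100 to 1450 for Sdc1_mut_Jhd2_KO against Sdc1_mut, 646 to 2142 for Sdc1_KO against Sdc1_mut, 804 to 2236 against Dpy30_KO, 1 to 2 for Dpy30_KO against Sdc1_mut and 580 to 1068 for the interaction. With limma-trend the share of calls that were higher was 24.5% for Jhd2_KO (46.2% before), 56.9% for the interaction (41.2%), 51.5% for Sdc1_mut_Jhd2_KO against Sdc1_mut (40.5%) and 45.5% for Sdc1_KO (55.5%). With an estimated correlation 0 lists were called in each of the 7 comparisons. The fry test called 22 lists in Sdc1_KO, 29 in Dpy30_KO, 26 in Sdc1_mut, 6 in Jhd2_KO, 31 in Sdc1_mut_Jhd2_KO against WT and 28 against Jhd2_KO. Depth was lowest in Jhd2_KO replicate 1 (8652878 fragments), where 3 counts in each library of the group correspond to 0.298 CPM.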

Other observations

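The tests of loss of Sdc1 function, of RNA lost in library preparation, of sporulating cells and of overlapping genes were chosen only after the result was seen. In none of the 7 comparisons was any of 12 gene lists called by camera with the preset correlation, or with an estimated one. Of 84 tests of these lists, 4 had an unadjusted camera p under 0.05, and the fry test called 10 of the 12 in at least 1 comparison (all but glycolysis and mitosis and M/G1). In the 3 direct comparisons between SDC1 mutants, which are not among the 7, camera called 7 of the 12 (0 with an estimated correlation). The lowest camera adjusted p over the 7 was 0.4 for the Set1 complex, 0.1 for JmjC proteins, 0.25 for the Set3 complex, 0.11 for Sir and telomere silencing factors, 0.081 for the zinc regulon, 0.26 for glycolysis and 0.13 for nitrogen catabolite repressed genes. It was 0.084 for DAN and TIR cell wall genes, 0.13 for cell wall integrity, 0.12 for mitosis and M/G1, 0.12 for the DNA damage response and 0.18 for strain markers and neighbours of the mutated loci.

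Iron regulon genes were higher in the groups with almost no mitochondrially encoded fragments (Dpy30_KO, Sdc1_mut and Sdc1_mut_Jhd2_KO). Loss of Sdc1 function itself is argued against as the whole cause, as 16 of 23 of these genes were lower in Sdc1_KO than in Sdc1_mut and 0 higher (15 in a fit of only these groups, 15 to 17 without 1 library), but it stays open as a part of it, as 5 of the 23 rose in Sdc1_KO, FIT1 by 1.68 ± 0.17 (a first test, on the median of -0.01 in Sdc1_KO, could not decide and was replaced). Mitochondrial RNA lost in library preparation is argued against as the only difference, as 37 of 43 nuclear respiratory genes were lower in Sdc1_mut than in Sdc1_KO. Whether such a loss took place beside it stays open. These genes cannot decide that, as 28 of the 43 fell in all 3 SDC1 mutants, Sdc1_KO with its mitochondrial transcripts included. For loss of mitochondrial DNA, the prediction written before was that CIT2, a gene raised when mitochondria fail, would be higher than in WT in all 3 of these groups and higher in Sdc1_mut than in Sdc1_KO, and it failed: CIT2 was called higher in 1 of the 3 (Sdc1_mut_Jhd2_KO, 0.82 ± 0.26, adjusted p = 0.016), with -0.58 ± 0.26 in Dpy30_KO and -0.34 ± 0.26 in Sdc1_mut, and Sdc1_KO stood above Sdc1_mut by 1.18 ± 0.26 (adjusted p = 0.0073). By the rule written before, this result went against loss of mitochondrial DNA. That rule was set aside on a ground not written before: CIT2 also rose in Sdc1_KO (0.85 ± 0.26, adjusted p = 0.016), which has mitochondrial transcripts. A rise there makes CIT2 a poor marker, but does not account for its missing rise in Dpy30_KO and Sdc1_mut. As CIT2 is 1 gene, loss of mitochondrial DNA may underlie the rise of the iron regulon but stays open.

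Of 44 meiosis and sporulation genes, 22 were higher and 3 lower in all 3 SDC1 mutants. The camera calls of this list did not hold with an estimated correlation. A rise of all genes of like mean level over the 12 libraries is argued against. The list median stood at the 99.99 percentile or higher of 10000 random lists matched on that mean (0.78, 0.93 and 0.78 against a random median of 0.16). Mutant libraries enter that mean, so a rise of all genes weakly expressed in WT stays open. Random genes were drawn independently, so the percentile does not allow for genes of a list moving together. Reads of annotated genes that overlap by at least 10% are argued against by 0 of 27 risen members that overlap another gene. Such overlaps are rare (231 of 6162 genes). Transcripts beyond the annotated bounds and unmatched identifiers were not checked, so their reads stay open. Meiotic or sporulating cells in the cultures stay open: 6 of 21 members under 5 CPM in WT were not higher in Sdc1_KO, and 0 of 3 regulators were called higher (highest 0.39), which cannot tell a small share of such cells from none, and the bound for this test was changed after the 6 was seen.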
